A study of Mus musculus with 32 samples.

How the data were processed

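RNA from whole marrow of the mouse femur was sequenced in 32 libraries, 1 per mouse, in 8 groups of 4. Per the labels, mice carrying an inducible diphtheria toxin receptor (iDTR) were crossed with adiponectin-Cre mice. The Cre-positive offspring are named DTRADQ, and their Cre-negative littermates served as controls. At 2 months of age the mice received 100 ng of diphtheria toxin (DT) each day for 1, 2 or 3 days, or no DT. Per the labels' protocols, total RNA was made into libraries with the Clontech SMARTer kit.

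The submitters' processing notes name bcl2fastq, STAR 2.0.4b, Subread and featureCounts 1.45, and the genome build GRCm38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Per the file headers, the authors deposited for each library a raw read count per gene, a CPM column and an RPKM column. The deposited CPM values equalled the counts divided by the library total and scaled to CPM, to within 4.4e-10. The deposited RPKM values equalled these divided by the gene length in kilobases, to a relative difference of 3.9e-14. The counts were used here, and the CPM and RPKM columns served only for this check. The tables held 41388 genes, of which 97.26% had a symbol. Genes that share reads with close relatives (Hba-a1 and Hba-a2, the Hbb genes, Ear1, Ear2, Ear6, Ear10 and the Ear pseudogenes, Bglap and Bglap2) are reported as uncertain, since the counting could split reads between them, as are genes that overlap a neighbour.

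Library totals ran from 8.97 M to 22.93 M counts with a median of 14.18 M. Low levels were bounded by a floor of 3 counts, and the ratio of a gene with 1 to 3 counts in a group is given with its 95% interval from the exact binomial test. Intervals cover counting error only. No pair of libraries was a copy of another, with at least 9.689 chi-square units per gene between libraries of a group. All libraries came from male mice, with Xist at most 1.047 CPM and Y-linked genes at least 85.1 CPM, so sex was not used as a covariate. The lane field of the labels reads 8 for the 8 libraries of day 3 and names all lanes for the other 24. Comparisons between day 3 and no DT, and the genotype-by-DT comparison at day 3, follow this label, and comparisons of genotypes on the same day do not.

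Counts were analysed in R 4.3.3. Genes passed filterByExpr of edgeR 4.0.16 with a minimum count of 10, which left 14527. Libraries were scaled by TMM, and 1 quasi-likelihood model held the 8 group means. The 13 contrasts were tested in this model, with two-sided p-values adjusted by Benjamini-Hochberg within each contrast and a threshold of 0.05. The contrasts were DTRADQ against controls at each of the 4 time points, the difference between the genotype effect after DT and without DT (genotype by DT) for each of the 3 days, and DT against no DT within controls and within DTRADQ. The standard errors (SE) printed are the absolute log2 change divided by the square root of the F statistic of its quasi-likelihood test. Values per group are CPM with TMM scaling, as mean ± SD with n = 4. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined.

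The 33 gene lists named in the plot of list medians and in the text covered adipocytes, stromal cells, bone, blood lineages, endothelium, skeletal muscle, cartilage and signalling or metabolic programmes. With at least 5 tested genes required, 32 were tested and the chondrocyte list with 4 was not. The test was camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 and adjustment over the lists within each contrast. Calls were repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction. For each list the members that passed over all genes are counted, and then those that passed when adjusted over the list alone. Named genes were chosen from the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 1 whose groups did not overlap, up to 3 members with the smallest p-values from each called list, and 13 genes fixed beforehand. Not every gene that met the rule is printed. Exceptions, named after their values were seen, are Hba-a1, Hba-a2, Alas2, Pdgfrb, Tnfrsf11b, Ibsp, Omd and Phex at day 3. Of the named genes that passed, 17 without DT, 35 at day 1, 35 at day 2 and 59 at day 3 had all 4 DTRADQ libraries on the same side of the control mean, which follows in part from the rule that chose them.

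The alternatives fixed beforehand were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts (28075 genes), a model of only the groups compared, voom with library weights, the mean of the skeletal muscle list as a covariate, the replicate number as a block, and leaving out each library in turn. The titles number the libraries 1 to 4 in each group, and no label says what a number stands for. Deviations from the group means of libraries with the same number had correlations above 0.1 in all 4 pairs for genotype without DT (0.144 to 0.178) and for DT in controls at day 1 (0.115 to 0.355). In both, the libraries numbered 2 and 4 did not correlate best with their own number, so pairing is not shown. The numbers were taken as possible pairs in these 2 comparisons, from the data alone, and not in the others. The main model holds no block. Leaving out control no-DT replicates 3 and 4 together was added after seeing the data. The same steps were tested on simulated counts in which a seeded set of genes was changed by known folds. For the comparison of genotypes at day 2, with 14527 genes, 19.4% of 1.5-fold, 68.7% of 2-fold and 86.4% of 4-fold changes were called, all in the right direction, and 5 of 14327 unchanged genes were called. For the genotype-by-DT comparison at day 2 the shares were 4.5%, 28.4% and 80.3%. All simulated libraries shared 1 base profile and 1 spread per gene. The real libraries differ in spread, with voom weights from 0.0848 in control no-DT replicate 4 to 2.05 in DTRADQ day 1 replicate 3. These shares therefore test the steps and do not give the error rates in the real data.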

Results

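Gene expression in whole femur marrow was counted in 32 libraries from male DTRADQ mice, whose adiponectin-Cre lineage is sensitive to DT, and from Cre-negative controls. Each genotype was sampled without DT and after 1, 2 or 3 days of daily DT, with 4 mice per group. Totals ran from 13.48 to 18.06 M counts in DTRADQ without DT, from 8.97 to 14.23 M in controls without DT, from 11.1 to 14.6 M and from 12.38 to 15.05 M in DTRADQ and controls at day 1, from 11.54 to 14.4 M and from 12.8 to 14.46 M at day 2, and from 15.74 to 19.85 M and from 21.05 to 22.93 M at day 3.

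Adipoq, the transcript of adiponectin and the marker of the targeted lineage (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028 in GRCm38), separated the genotypes after DT in every library. It lay between 0.292 and 1.07 CPM in DTRADQ at day 1 against 36.2 to 66.3 CPM in controls, between 0.221 and 0.979 against 55.0 to 58.5 CPM at day 2, and between 0.264 and 0.600 against 32.1 to 54.3 CPM at day 3. Without DT it lay between 28.6 and 47.6 CPM in DTRADQ and between 43.2 and 134 CPM in controls.

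**Figure D1:**
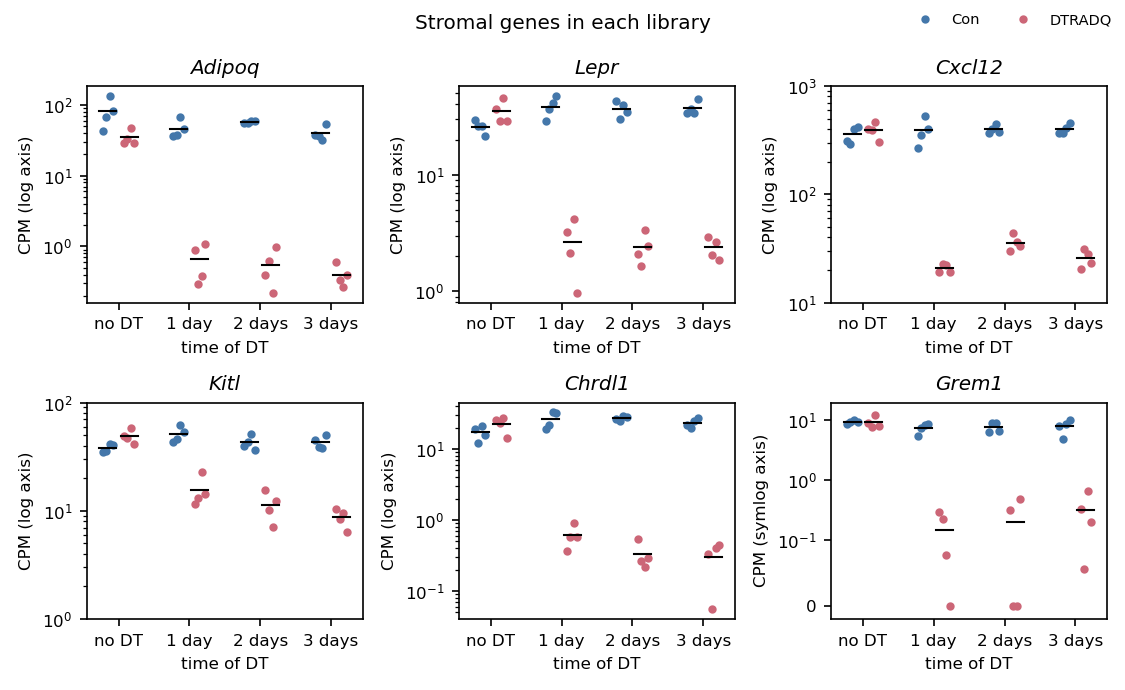
Expression of 6 stromal genes in each library, in CPM on log axes (Grem1 on a symlog axis that includes 0), by days of DT. Points are mice, lines are group means with n = 4, and in each panel all 4 DTRADQ libraries lie below all 4 control libraries on each day of DT.

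The first question was what 1 day of DT changes in marrow when the adiponectin lineage is the target. The genes that mark marrow stromal cells of this lineage fell almost as a block: 24 of 26 fell and 2 did not pass, with 24 when adjusted over the list alone (median log2 change −3.47, adjusted p = 4.5e-60, and adjusted p = 2.1e-07 with an estimated correlation). Cxcl12, the chemokine that retains blood stem cells and B cell precursors (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), went from 388 ± 109 CPM (SD, n = 4) in controls to 20.8 ± 1.86 CPM, a log2 change of −4.22 (SE 0.20, adjusted p = 5.3e-16). Adipoq changed by −6.17 (SE 0.37), Lepr, the leptin receptor, by −3.84 (SE 0.26), and Kitl, the stem cell factor, by −1.73 (SE 0.20). Igfbp5 changed by −4.96 and Lpl, lipoprotein lipase, by −0.81 (SE 0.17, adjusted p = 0.0025).

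Lists of BMP antagonists and of RANKL, OPG and WNT regulators were called lower too. Of 11 BMP antagonists 5 fell and 6 did not pass, with 5 when adjusted over the list alone (median −0.36, mean −1.82, adjusted p = 3.2e-08, and adjusted p = 0.0026 with an estimated correlation). Chrdl1 changed by −5.41 (SE 0.29), Grem1 by −5.52 (SE 0.48) and Fstl1 by −1.73 (SE 0.19). Of 15 RANKL, OPG and WNT regulators 3 fell, or 5 when adjusted over the list alone (median −0.31, adjusted p = 0.0022, and adjusted p = 0.0141 with an estimated correlation): the WNT inhibitors Sfrp4 (−4.22) and Sfrp1 (−3.37) and Il34, a ligand of the CSF1 receptor (−4.61). Of 24 osteoblast and osteocyte genes 5 fell and 1 rose, or 8 and 3 when adjusted over the list alone (median −0.52, adjusted p = 0.0018, but adjusted p = 0.1932 with an estimated correlation). Ibsp (−3.01) and Ogn (−2.24) fell, and Spp1, osteopontin, rose by 1.49. The BMP target Id1 (0.32, adjusted p = 0.3769), the osteoblast factor Sp7 (−0.89, adjusted p = 0.5500) and Bglap (0.47, adjusted p = 0.7354, reads shared with Bglap2) did not pass.

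Some chemokines and immediate early genes rose on the same day. Ccl2, which recruits monocytes, went from 3.15 ± 0.536 to 93.5 ± 43.0 CPM (log2 change 4.89, SE 0.52, adjusted p = 6.1e-08), Ccl7 changed by 4.27 (SE 0.44), and Cxcl1, which recruits neutrophils, by 8.53 (SE 1.36). Of 21 inflammatory cytokine and NF-kB response genes 6 rose and 15 did not pass, with 7 when adjusted over the list alone (median 0.39, adjusted p = 1.3e-10, and adjusted p = 0.0159 with an estimated correlation). Of 18 ERK response and immediate early genes 6 rose and 1 fell, with 8 and 1 when adjusted over the list alone (median 0.46, adjusted p = 1.3e-05, and adjusted p = 0.0026 with an estimated correlation). Egr1 changed by 3.70 (SE 0.45) and Jun by 3.02 (SE 0.41). The matrix list members Ccn1 (3.87) and Tagln (2.67) rose, while the fibroblast and matrix list did not pass as a whole (5 rose, 6 fell, 13 did not pass, adjusted p = 0.2240).

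Blood cell lists were called on the same day. Of 22 T and NK cell genes 8 fell and 14 did not pass, with 11 when adjusted over the list alone (median −0.66, adjusted p = 2.4e-07, but adjusted p = 0.0790 with an estimated correlation). Trac changed by −1.59 (SE 0.35). Of 17 basophil, mast cell and eosinophil genes 6 rose, also 6 when adjusted over the list alone (median 0.57, adjusted p = 4.3e-07, but adjusted p = 0.0790 with an estimated correlation). Prg2, an eosinophil granule protein, changed by 1.21 (SE 0.27) and Ear6, which shares reads with its relatives, by 1.31. Of 18 megakaryocyte and platelet genes 3 rose, or 15 when adjusted over the list alone (median 0.58, adjusted p = 1.2e-11, and adjusted p = 0.0317 with an estimated correlation). Of 18 stem and progenitor genes 2 rose and 1 fell, or 3 and 2 when adjusted over the list alone (median 0.35, adjusted p = 0.0022, and adjusted p = 0.0141 with an estimated correlation). The list of mature neutrophil genes was higher with 2 of 22 that rose, or 5 when adjusted over the list alone (median 0.53, adjusted p = 3.2e-08, but adjusted p = 0.0899 with an estimated correlation).

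In all, 567 of 14527 genes passed at day 1, 129 higher and 438 lower. Without control replicate 3 the count was 327, with 56 higher and 271 lower, and without DTRADQ replicate 2 it was 372. The fit of only these 2 groups called 1010 (351 higher and 659 lower), voom with library weights 2150 (928 and 1222), DESeq2 757 (244 and 513), and the fit without control no-DT replicates 3 and 4, chosen after seeing the data, 1340 (463 and 877). The 10 most abundant genes took 25.19% to 25.93% of the counts in DTRADQ and 21.86% to 22.05% in controls at day 1.

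After 2 days the stromal genes stayed low: 24 of 26 fell, also 24 when adjusted over the list alone (median −2.48, adjusted p = 1.8e-39, and adjusted p = 1.9e-05 with an estimated correlation). Cxcl12 was at 35.9 ± 6.05 CPM against 400 ± 34.9 CPM in controls (log2 change −3.48, SE 0.19). Adipoq changed by −6.74 (SE 0.38), Lepr by −3.92, Kitl by −1.92, Igfbp5 by −5.64 and Cfd, adipsin, by −5.33 (SE 0.81). Of the BMP antagonists 5 fell and 6 did not pass, or 6 fell and 1 rose when adjusted over the list alone (median −0.49, mean −1.57, adjusted p = 0.0013, but adjusted p = 0.1204 with an estimated correlation), with Chrdl1 at −6.31 and Grem1 at −5.31.

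The matrix and endothelial lists were called higher at day 2. Of 24 fibroblast and matrix genes 8 rose and 4 fell, or 9 and 4 when adjusted over the list alone (median 0.29, adjusted p = 0.0153, but adjusted p = 0.4413 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle cells and myofibroblasts, went from 1.33 ± 0.305 to 22.7 ± 9.84 CPM (log2 change 4.09, SE 0.30). Ccn1 changed by 4.10, Ccn2 by 3.06 and Timp1, an inhibitor of matrix proteases, by 2.82. Of 20 endothelial genes 4 rose, or 6 when adjusted over the list alone (median 0.15, adjusted p = 0.0359, but adjusted p = 0.4921 with an estimated correlation), with Ecscr at 1.36 and Emcn at 1.30. The matrix list lost its call without DTRADQ replicate 2 (adjusted p = 0.0601). The endothelial list lost it without DTRADQ replicate 2 (adjusted p = 0.1403), DTRADQ replicate 4 (0.1096) or control replicate 2 (0.0725). Both calls were lost with no filter on low counts (adjusted p = 0.0696 for the matrix and 0.0811 for the endothelial list) and with only these 2 groups (0.1018 and 0.1092).

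The granulocyte lists were higher and the B lineage and DNA replication lists lower at day 2. Of 17 neutrophil precursor granule genes 4 rose, or 8 when adjusted over the list alone (median 0.67, adjusted p = 1.9e-05), with Lcn2 at 0.94 (SE 0.20). Of 22 mature neutrophil genes 4 rose, or 14 when adjusted over the list alone (median 0.69, adjusted p = 4.4e-08), with Ly6g at 0.84 and Retnlg at 1.03. Of 25 B lineage genes 5 fell, or 6 when adjusted over the list alone (median −0.42, adjusted p = 1.9e-05), with Fcer2a at −1.55 and Dntt, the terminal transferase of lymphoid precursors, at −1.21. Of 22 DNA replication genes 6 fell, or 15 when adjusted over the list alone (median −0.39, adjusted p = 3.4e-08), with Ccne1, cyclin E1, at −1.17. Of 18 megakaryocyte and platelet genes 6 rose, or 13 when adjusted over the list alone (median 0.59, adjusted p = 3.8e-09), with Thbs1 at 1.21. These 5 calls were lost with an estimated correlation (adjusted p = 0.2530, 0.1447, 0.3298, 0.1422 and 0.1204 in that order). The T and NK cell list was not called at day 2 (4 of 22 fell, or 6 when adjusted over the list alone, median −0.25, adjusted p = 0.1691).

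Ccl2 (3.60, SE 0.51) and Ccl7 (3.22, SE 0.43) remained higher at day 2, and 4 of 21 inflammatory genes rose, also 4 when adjusted over the list alone (median 0.55, adjusted p = 2.7e-05, but adjusted p = 0.1447 with an estimated correlation). DTRADQ replicate 1 stood apart with 87.9 CPM of Ccl2 against 14.9 to 19.6 in the other 3, and the call of Cxcl1 (5.97) was lost without that library (1.94, adjusted p = 0.3737). In all, 1238 genes passed, 639 higher and 599 lower, and with DESeq2 979 were higher and 721 lower. The count was 569 without control replicate 4, 590 without control replicate 3, 592 without DTRADQ replicate 3, 693 without DTRADQ replicate 2 and 1477 without DTRADQ replicate 1. The fit of only these 2 groups called 2621, voom with library weights 3608, and the fit without control no-DT replicates 3 and 4 called 2887. At day 2 the 10 most abundant genes took 25.1% to 30.19% of the counts in DTRADQ and 19.4% to 21.96% in controls, and mitochondrial genes 1.506% to 1.825% and 1.911% to 2.418%.

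After 3 days the stromal loss stood beside a broad rise of matrix genes. Of 26 stromal genes 21 fell and 1 rose, also 21 and 1 when adjusted over the list alone (median −2.45, adjusted p = 1.5e-18, and adjusted p = 0.0034 with an estimated correlation). Cxcl12 was at 25.8 ± 4.92 CPM against 403 ± 42.2 CPM (log2 change −3.97, SE 0.20), Adipoq changed by −6.61 (SE 0.38), Lepr by −3.97, Kitl by −2.31, Chrdl1 by −6.23 and Grem1 by −4.71. Pdgfrb, a receptor of pericytes and fibroblasts, was the member that rose (0.42, adjusted p = 0.0436), a call lost without DTRADQ replicate 2 (adjusted p = 0.1965), 3 (0.0718) or 4 (0.0861) and without control replicate 1 (0.1216) or 4 (0.1382). Cfd gave 1 read in the DTRADQ libraries against 957 in controls, a control-to-DTRADQ ratio of 810 with a 95% interval of 145 to 32000. Lpl (0.21, adjusted p = 0.3894) and Pparg (−0.51, adjusted p = 0.0545) did not pass.

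Of 24 fibroblast and matrix genes 15 rose and 2 fell at day 3, or 15 and 3 when adjusted over the list alone (median 0.91, adjusted p = 5.1e-11, but adjusted p = 0.0598 with an estimated correlation). Tagln rose from 1.00 ± 0.333 to 58.1 ± 15.7 CPM (log2 change 5.84, SE 0.31), Timp1 by 4.35, Ccn1 by 4.15 and Thbs2 by 3.38. Of 24 osteoblast and osteocyte genes 11 rose and 4 fell, also 11 and 4 when adjusted over the list alone (median 0.64, adjusted p = 0.0014, but adjusted p = 0.1784 with an estimated correlation). With the muscle covariate the osteoblast call was lost (adjusted p = 0.0975). Col1a1, the main chain of bone collagen, rose from 34.5 ± 6.18 to 186 ± 43.2 CPM (log2 change 2.43, SE 0.49), Postn by 3.64 and Cthrc1 by 5.49. Ogn (−1.69), Ibsp (−1.35), Omd (−1.26) and Phex (−2.35) fell, while Bglap (0.40, adjusted p = 0.6355) and Sp7 (−0.21, adjusted p = 0.8126) did not pass. Of 20 endothelial genes 12 rose, also 12 when adjusted over the list alone (median 0.71, adjusted p = 5.9e-07, but adjusted p = 0.1311 with an estimated correlation), with Emcn at 2.14, Ecscr at 2.13 and Robo4 at 1.69. Skeletal muscle genes moved with these groups in the same libraries: 13 of 16 rose, or 14 when adjusted over the list alone (median 2.14, adjusted p = 1.1e-08, but adjusted p = 0.1625 with an estimated correlation). Myl1 was at 55.1 ± 58.7 CPM against 2.11 ± 2.17 CPM, and Ckm changed by 4.32 (SE 0.94).

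Red cell genes and cell division genes fell at day 3. Of 26 erythroid genes 21 fell and 3 rose, or 21 and 4 when adjusted over the list alone (median −1.72, adjusted p = 3.3e-12, but adjusted p = 0.1593 with an estimated correlation). Tfrc, the transferrin receptor, went from 439 ± 79.7 to 100 ± 18.3 CPM (log2 change −2.13, SE 0.27), Ermap changed by −1.94 and Add2 by −1.85. The 3 that rose are expressed late in red cell maturation: Alas2 (1.27), Hba-a1 (1.27) and Hba-a2 (1.35), the last pair sharing reads. Of 22 cell division genes 19 fell, or 20 when adjusted over the list alone (median −0.81, adjusted p = 3.3e-12, but adjusted p = 0.0598 with an estimated correlation), with Mki67 from 656 ± 95.2 to 266 ± 25.1 CPM (log2 change −1.30, SE 0.18) and Cenpf at −1.28. Of 22 DNA replication genes 21 fell, or 22 when adjusted over the list alone (median −0.76, adjusted p = 5.1e-11, but adjusted p = 0.0598 with an estimated correlation), with Ccne1 at −1.68.

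Other lists were called at day 3 too. Of 17 basophil, mast cell and eosinophil genes 9 rose (median 0.70, adjusted p = 2.6e-04), of 18 megakaryocyte and platelet genes 9 rose (median 0.58, adjusted p = 3.3e-06), and of 21 inflammatory genes 4 rose (median 0.38, adjusted p = 1.3e-04), with Ccl7 at 3.10, Ccl2 at 2.35 and Csf1 at 0.89. When adjusted over the list alone the counts were 9, 13 and 4, and the 3 calls were lost with an estimated correlation (adjusted p = 0.1784, 0.1601 and 0.1601). In all, 3330 genes passed, 1279 higher and 2051 lower, and no left-out library moved the total by more than 1.5 times, though without control replicate 4 the higher genes numbered 755. The fit of only these 2 groups called 5143 and voom with library weights 5724. At day 3 the 10 most abundant genes took 27.16% to 30.87% of the counts in DTRADQ and 22.32% to 24.12% in controls, and mitochondrial genes 1.599% to 1.911% and 2.075% to 2.873%.

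**Figure D2:**
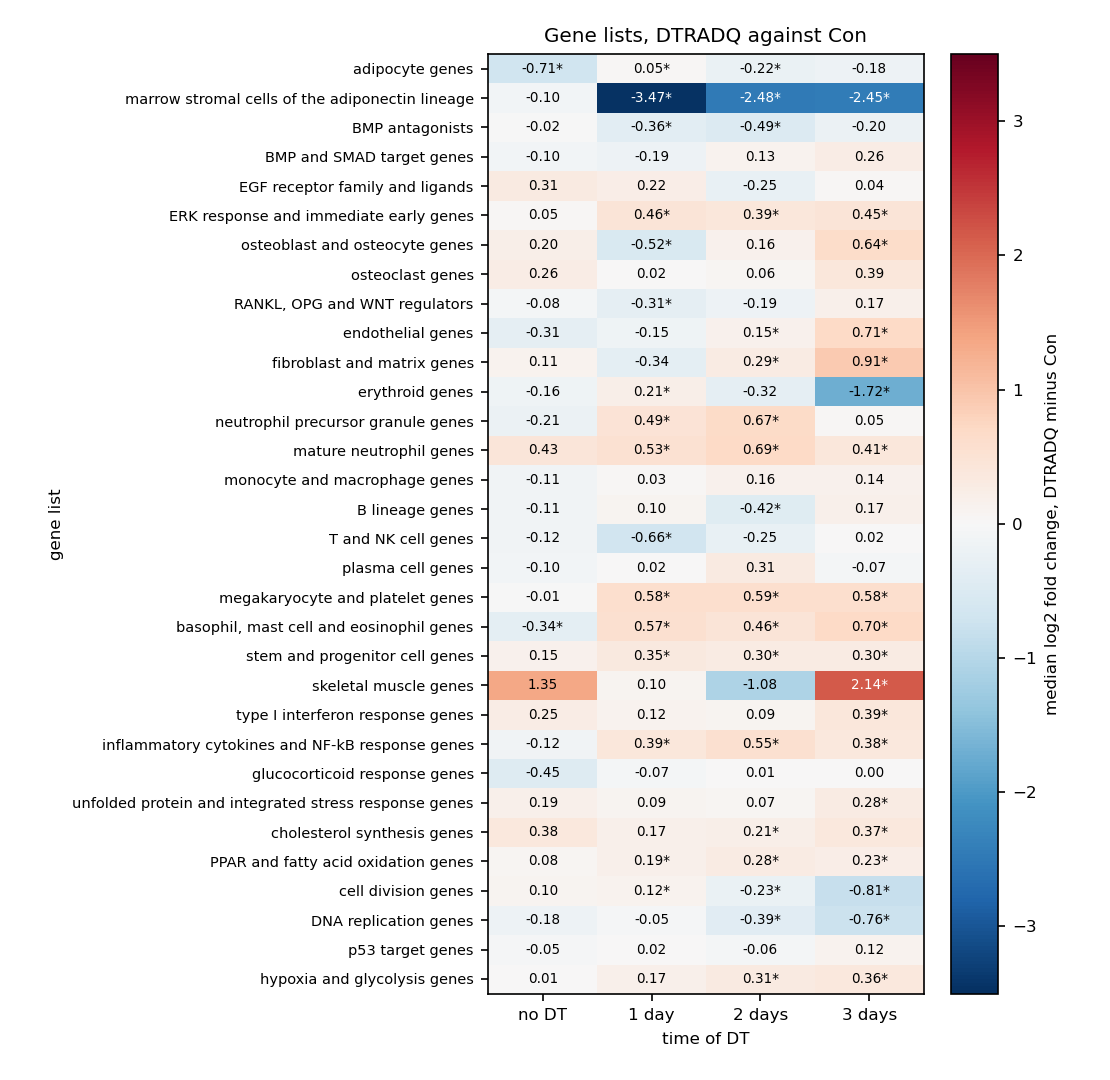
Median log2 fold change, DTRADQ minus control, of the tested genes of each of the 32 tested lists without DT and after 1, 2 and 3 days. Colour gives the median on the scale at the side, and an asterisk marks a list with an adjusted p below 0.05 by camera with its preset correlation. The stromal list is lowest on each day of DT (−3.47, −2.48 and −2.45).

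**Figure D3:**
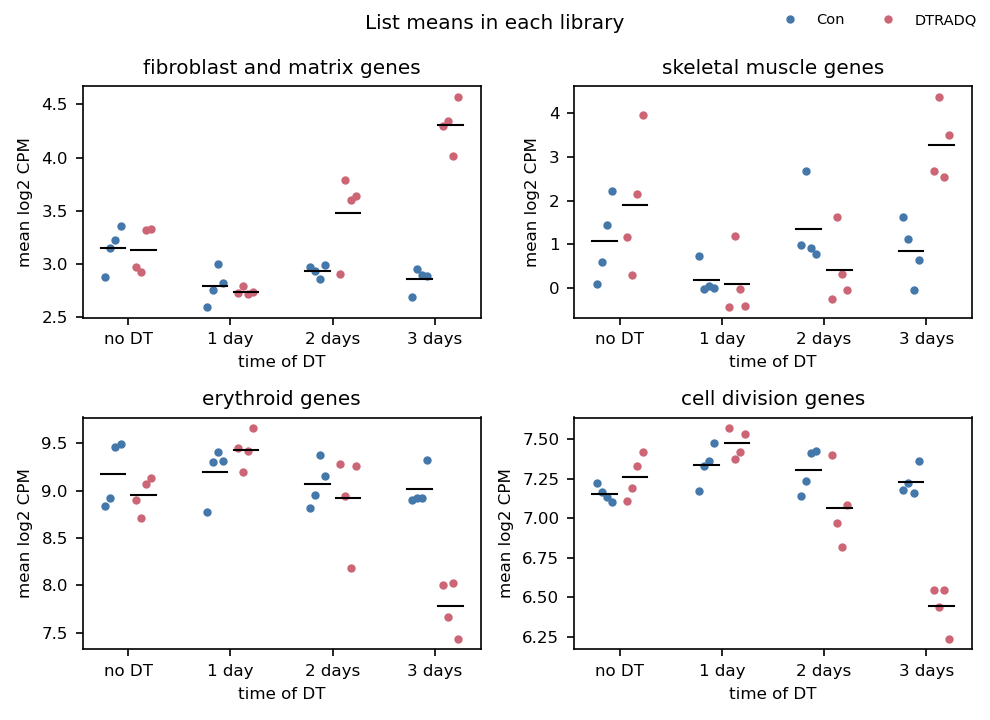
Mean log2 CPM of 4 lists in each library by days of DT. Points are mice and lines are group means with n = 4. At day 3 the matrix and skeletal muscle scores of DTRADQ lie above the controls of that day, and the erythroid and cell division scores lie below them.

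The genotypes were also compared without DT, which shows the state from which the response to DT starts. Stromal genes were close to controls: of 26, 4 fell, 1 rose and 21 did not pass, or 2 fell and 1 rose when adjusted over the list alone (median −0.10, adjusted p = 0.8419), with Cxcl12 at 0.13, Lepr at 0.42, Kitl at 0.36, Chrdl1 at 0.39 and Grem1 at 0.00, none of them past the threshold. Adipoq was lower (−1.24, SE 0.25, adjusted p = 5.5e-04), as were Fabp4, a fatty acid carrier of fat cells (−1.74), and Cfd (−2.51). Hbegf, the mouse gene of the growth factor that serves as DT receptor in other species, was at 2.26 ± 0.681 CPM in DTRADQ and 0.740 ± 0.239 CPM in controls (log2 change 1.54, SE 0.43, adjusted p = 0.0084). After DT its difference did not pass (0.36, 0.97 and 0.86 at days 1, 2 and 3, adjusted p = 0.7416, 0.1394 and 0.0915). Whether reads of the inducible DT receptor were counted under Hbegf was not tested. Of 15 adipocyte genes 6 fell, or 8 when adjusted over the list alone (median −0.71, adjusted p = 0.0378), and of 17 basophil, mast cell and eosinophil genes 7 fell, also 7 when adjusted over the list alone (median −0.34, adjusted p = 0.0378). Both lists had adjusted p = 0.9915 with an estimated correlation, and 0 lists were called with the replicate number as a block or with the muscle covariate. With no filter on low counts 6 lists were called, all higher, and these 2 calls of lower lists were lost (adjusted p = 0.2161 and 0.1827). Col1a1 rose (1.48, adjusted p = 0.0235), with DTRADQ replicate 4 at 219 CPM against 28.6 to 43.6 CPM in the other 3. Its call was lost without that library (0.30, adjusted p = 0.6179), control replicate 1 (1.22, adjusted p = 0.0576) or control replicate 2 (1.26, adjusted p = 0.0694). Slc39a1, a zinc transporter (2.05), and Wtap (2.02) were among the larger rises, and Pnck (−2.91) and Rnase12 (−2.30) were, with Cfd, among the larger falls. Without control replicate 4 Pnck was at −1.52.

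The comparison without DT called 3944 genes, 1849 higher and 2095 lower, but its control libraries differed among themselves. The 10 most abundant genes took 22.68%, 28.61%, 37.41% and 50.69% of the counts in control replicates 1 to 4, against 22.79% to 24.79% in DTRADQ. The count was 5939 without control replicate 1, 2285 without control replicate 3, and 1900 without replicates 3 and 4. The edgeR fit of only these 2 groups called 0, with 3068 at an unadjusted p under 0.05, while DESeq2 called 4291. The main fit shares 1 spread per gene over all 8 groups, so its adjusted p-values without DT may be too small. The adipocyte call was lost without DTRADQ replicate 3 (adjusted p = 0.0602) or 4 (0.1876) and without control replicate 1 (0.0790), 2 (0.0703), 3 (0.0507) or 4 (0.0658). The eosinophil call was lost without DTRADQ replicate 3 (0.0684) or 4 (0.2632) and without control replicate 1 (0.2206) or 2 (0.1031).

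**Figure D4:**
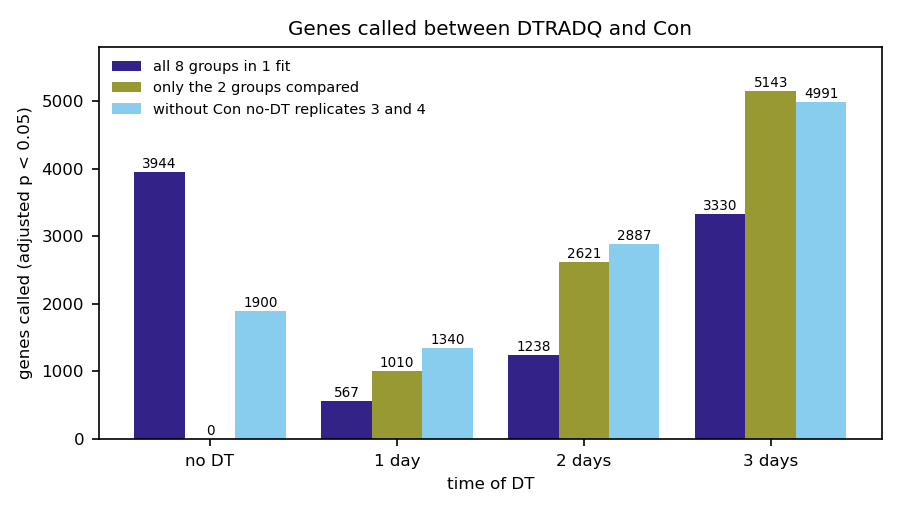
Number of genes with an adjusted p below 0.05 between DTRADQ and controls, by days of DT, in the fit of all 8 groups, in the fit of only the 2 groups compared, and without control no-DT replicates 3 and 4. Without DT the 3 fits called 3944, 0 and 1900 genes, and at day 3 they called 3330, 5143 and 4991.

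Genotype by DT asks whether the genotype difference after DT departs from that without DT. It did for stromal genes on each day: 20, 17 and 15 of 26 were lower than the difference without DT at days 1, 2 and 3, or 21, 20 and 17 when adjusted over the list alone, where 1 was higher at day 3 (adjusted p = 5.8e-31, 1.4e-26 and 9.5e-15, and adjusted p = 1.0e-04, 3.1e-04 and 0.0127 with an estimated correlation). For Cxcl12 the terms were −4.35 (SE 0.26), −3.61 (SE 0.26) and −4.10 (SE 0.26), and for Adipoq −4.93 (SE 0.46), −5.49 (SE 0.47) and −5.37 (SE 0.46). Ccn2 was higher by 3.62, 4.55 and 5.41, while its genotype difference after DT was 2.14, 3.06 and 3.92. The rest of each term comes from the comparison without DT, where Ccn2 was lower in DTRADQ. At day 3 the matrix list rose beyond the difference without DT (13 of 24 higher and 2 lower, or 16 and 3 when adjusted over the list alone, adjusted p = 6.0e-07, but adjusted p = 0.1788 with an estimated correlation), with Tagln at 5.55. Cell division genes fell beyond it (16 of 22, or 18 when adjusted over the list alone, adjusted p = 1.2e-09, but adjusted p = 0.1788 with an estimated correlation), with Kif11 at −1.36, as did erythroid genes (17 of 26 lower and 5 higher, or 20 and 5 when adjusted over the list alone, adjusted p = 1.9e-06, but adjusted p = 0.4604 with an estimated correlation), with Hemgn at −2.81. The day 3 libraries carry a lane label of their own. The terms for Pparg, Hbegf, Id1, Sp7, Col1a1 and Bglap did not pass on any day, and Col1a1 was at 0.95 (adjusted p = 0.3440) at day 3. The 3 comparisons called 1793, 1613 and 3056 genes. Without control no-DT replicate 1 the counts were 3951 and 3749 at days 1 and 2, and with only the 4 groups compared they were 449, 356 and 1669.

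DT was also compared with no DT in control mice, and all 3 comparisons rest on the same 4 control libraries without DT. In their replicates 3 and 4 the 10 most abundant genes took 37.41% and 50.69% of the counts, globin genes 19.67% and 26.386% and genes that overlap rRNA 3.068% and 11.163%. Against controls without DT at days 1, 2 and 3, Cxcl12 was at 0.12, 0.16 and 0.17 and Kitl at 0.43, 0.17 and 0.19, none past the threshold. Chrdl1 rose at day 1 (0.62, adjusted p = 0.0218) and day 2 (0.66, adjusted p = 0.0174) and Lepr at day 1 (0.56, adjusted p = 0.0434). These calls were lost without control no-DT replicate 2 (Chrdl1 at 0.53 and 0.56, Lepr at 0.61, adjusted p = 0.0606, 0.0561 and 0.0517). At day 1 they were also lost without control DT replicate 3 (Chrdl1 0.50, Lepr 0.53, adjusted p = 0.0858 for each) or 4 (0.52 and 0.44, adjusted p = 0.0794 and 0.1486), and that of Lepr without control no-DT replicate 3 (0.61, adjusted p = 0.0607) or 4 (0.51, adjusted p = 0.0844) or control DT replicate 2 (0.59, adjusted p = 0.0599). Adipoq was lower at day 1 (−0.82, adjusted p = 0.0120) and day 3 (−1.03, adjusted p = 0.0023) and did not pass at day 2 (−0.53, adjusted p = 0.1170). Its call at day 1 was lost without control no-DT replicate 3 (−0.42, adjusted p = 0.1944), and at day 3 the change was −0.65 without it (adjusted p = 0.0449). The 1 list called was that of basophil, mast cell and eosinophil genes, of which 8, 8 and 7 of 17 fell, or 8, 9 and 8 when adjusted over the list alone, where 1 rose at day 3 (adjusted p = 0.0021, 7.2e-05 and 0.0013, but adjusted p = 0.9267, 0.9625 and 0.9105 with an estimated correlation). It was lost without control no-DT replicate 1 at day 1 (adjusted p = 0.0933) and day 3 (0.0634). With no filter on low counts 9, 11 and 10 lists were called higher and 1, 1 and 0 lower, and the call was lost at day 3 (adjusted p = 0.0637). Ear6, which shares reads with its relatives, changed by −2.00, −2.06 and −2.02. Cadps2, a secretion factor, changed by −4.61, −4.49 and −4.61, and it was at 2060 CPM in control no-DT replicate 4 against 34.7 to 334 CPM in the other 3. Without that library its changes were −2.53, −2.41 and −2.52. The comparisons called 4859, 4109 and 4391 genes, 890, 646 and 860 with only the 2 groups compared, and 3148, 2927 and 3373 without control no-DT replicates 3 and 4. Since the baseline is shared, no overlap between them is given. At day 3 the lane label differs between the groups compared as well.

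Within DTRADQ, DT lowered 24, 24 and 21 of 26 stromal genes at days 1, 2 and 3 against DTRADQ without DT (median −3.62, −2.73 and −2.56), also 24, 24 and 21 when adjusted over the list alone, where 1 rose at day 3 (adjusted p = 6.6e-07, 1.1e-05 and 0.0033 with an estimated correlation). Inflammatory genes rose, 5, 5 and 12 of 21, or 8, 7 and 12 when adjusted over the list alone (adjusted p = 1.5e-07, 1.5e-04 and 5.9e-07, but adjusted p = 0.0670, 0.2161 and 0.0959 with an estimated correlation). Skeletal muscle genes fell at day 1 (6 of 16, or 13 when adjusted over the list alone, adjusted p = 5.6e-04, but adjusted p = 0.3982 with an estimated correlation), where DTRADQ no-DT replicate 4 had the highest muscle score outside DTRADQ at day 3 (3.957). These comparisons called 796, 1324 and 4264 genes. The day 3 libraries carry another lane label than those without DT, so lane and DT cannot be told apart there. With the muscle covariate the counts were 295 at day 1, 42 higher and 253 lower, and 763 at day 2. At day 1, 183 were higher and 613 lower, against 374 and 699 with DESeq2. Leaving out 1 library each time, the total at day 1 was 513 without DTRADQ no-DT replicate 3 and 437 without its replicate 4. It was 478 without day 1 replicate 3 and 465 without day 1 replicate 4. The total at day 2 was 725 without no-DT replicate 3 and 545 without no-DT replicate 4. It was 774 without day 2 replicate 2 and 652 without day 2 replicate 3. Fits of only the 2 groups compared called 1755 genes at day 1 and 2192 at day 2.

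The comparisons of genotypes on different days share no libraries. They do share 1 estimate of the spread per gene, so their calls are not independent, and the overlaps were not tested. Genes lower at day 1 and at day 2 numbered 223, against 18.1 for independent lists, genes lower at days 1 and 3 numbered 193 against 61.8, and genes lower at days 2 and 3 numbered 446 against 84.6. For higher genes the overlaps were 78 against 5.70, 69 against 11.4 and 343 against 56.3. On all 3 days 159 genes were lower and 53 were higher.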

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

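Among the tests below, those of the muscle scores, of matrix genes on both days, and of a swap and of the position of DTRADQ day 2 replicate 1 were chosen only after the result was seen.

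The comparison of genotypes without DT called 3944 genes, and the control libraries without DT differ in how many counts a few genes take. Over these genes the median change in the called direction was 0.18 against control replicate 1 alone, and 0.69, 1.09 and 1.20 against replicates 2, 3 and 4. A difference between genotypes that is there with and without DT stays open. At day 1 the median over the same genes was 0.08, against 0.76 without DT, which lay under the bound set beforehand. The genes were chosen by their values without DT, so a smaller median in other libraries follows in part from that choice. With 64.2% of them of the same sign at day 1, the test does not decide. It also stays open that libraries in which a few genes take most counts may account for much of the count. Replicate 1 has the lowest share in the 10 most abundant genes (22.68%) and replicate 4 the highest (50.69%). A difference of the mice that ends with DT was not tested.

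Matrix, osteoblast and skeletal muscle genes were higher together in DTRADQ at day 3. Skeletal muscle carried into the samples, as far as the muscle score follows it, is argued against for the matrix genes. Of these 13 rose with the score as covariate (median 1.02, against 0.91 without it). Other tissue carried along that the score does not follow was not tested. Of the osteoblast genes 6 rose with the covariate (median 0.29, against 0.64), and their list lost its call (adjusted p = 0.0975). Here 6 lies between the bounds set beforehand, at most 3 and at least 8. Carried muscle therefore cannot be told apart from a change in bone cells or in other cells that express these genes. Ogn, Ibsp, Omd and Phex of this list fell at day 3, while most called members rose. For the muscle genes themselves carried muscle stays open, since 3 of the 4 libraries had a muscle score inside the range of the other 28. Only 2 of those lay above the lowest at day 3 (2.536), DTRADQ no-DT replicate 4 at 3.957 and control day 2 replicate 2 at 2.683. Of 20 listed muscle genes 16 passed the filter on low counts, with Myl1 at 55.1 ± 58.7 and Tnnt3 at 46.3 ± 45.1 CPM at day 3. A response of mice with toxin-sensitive cells also stays open for the matrix genes, since all 8 that rose at day 2, when the muscle list had a median of −1.08, rose at day 3.

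DTRADQ day 2 replicate 1 lies nearer to the day 1 libraries than to its own group, with a mean squared log2 distance of 0.141 to the mean of day 1 and 0.239 to the mean of day 2 replicates 2 to 4. A swap with a day 1 library is argued against, since 0 of the 4 day 1 libraries lie nearer to day 2. A wrong day label of this library alone stays open: on an axis from 0 at day 1 to 1 at day 2 it lies at 0.29, inside the range of the day 1 libraries (0.06 to 0.40) and below the others of day 2 (0.56 to 0.80). A slower response of this mouse would give the same position and may equally account for it, which was not tested apart. Without this library 1477 genes were called at day 2.

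Each count was compared with other splits of the same libraries, with a share under 0.05 as the bound. No correction was made for the number of counts judged, and 1 of 35 is the lowest share that 35 splits can give. Chance is argued against for the number of genes called between genotypes at day 1 (1 of 35 splits of the libraries, 567 genes, highest other 1), day 2 (1 of 35, 1238, highest other 124) and day 3 (1 of 35, 3330, highest other 0). The same holds for DT within DTRADQ at day 1 (1 of 35, 796, highest other 1), day 2 (1 of 35, 1324, highest other 21) and day 3 (1 of 35, 4264, highest other 2). At day 3 the lane label parts these groups in the same way as DT. Chance cannot be excluded for genotype without DT (3 of 35, 3944, highest other 4699). The other splits with as many genes there put control replicate 1 with DTRADQ libraries, which points to a structure of the samples. For DT in controls the share was under 0.05 at day 2 (1 of 35, 4109, highest other 3947) and not at day 3 (2 of 35, 4391, highest other 4407). At day 1 the real split ranked 1 of 35 (4859, highest other 4721) when pairs are left aside. Chance is not excluded by these ranks. The highest other splits put control no-DT replicate 1 with the DT libraries, and they call nearly as many genes, so these counts too follow a structure of the samples. Where the numbers were taken as pairs, only 8 splits part all 4 pairs as the real one does, too few for a share under 0.05. Among these the highest other count was 2912 for DT in controls at day 1 and 2679 for genotype without DT, and the splits above these part fewer pairs. For genotype by DT chance cannot be excluded at day 1 (5 of 100, 1793, highest other 3408) or day 2 (5 of 100, 1613, highest other 2709). At day 3 the share was under 0.05 (2 of 100, 3056, highest other 3428), but chance is not excluded there either. The split with 3428 genes put control no-DT replicate 1 with DTRADQ libraries, so this count too may follow a structure of the samples. These 100 splits did not hold the numbers as pairs, and the day 3 lane label was the same in all of them.

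For the number of lists called, the share was under 0.05 only for DT within DTRADQ at day 1 (1 of 35, 18 lists, highest other 16), again with no correction for the number of counts judged. Chance cannot be excluded for genotype without DT (30 of 35, 2 lists, highest other 8), at day 1 (5 of 35, 16, highest other 18), day 2 (2 of 35, 18, highest other 21) and day 3 (5 of 35, 19, highest other 23). Nor can it be for DT within DTRADQ at day 2 (4 of 35, 15, highest other 18) and day 3 (2 of 35, 17, highest other 22). The same holds for genotype by DT (29, 26 and 23 of 100 at days 1, 2 and 3, with 8, 10 and 12 lists, highest other 15, 19 and 20) and for DT in controls (33, 32 and 33 of 35, with 1 list each day, highest other 11, 9 and 10).

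The genotype effect after DT differed from that without DT, by the test of the difference itself, in 1793 genes and 8 lists at day 1, or 1 list with an estimated correlation. The larger terms were 5.10 for Ccl7, 5.01 for Ccl2, 4.77 for Cadps2, 4.70 for Gprin1, 3.62 for Ccn2 and 3.60 for Ccn1, and −5.81 for Dpep1, −5.80 for Chrdl1, −5.51 for Grem1, −5.47 for Gdpd2, −5.46 for Fmo2, −4.93 for Adipoq, −4.76 for Igfbp5, −4.35 for Cxcl12 and −4.26 for Lepr. Others were 2.61 for Ear6, 2.31 for Hba-a1 (both sharing reads), 1.16 for Clec1b, −2.20 for Ogn and −2.09 for Kitl. Globin genes took 7.496%, 10.041%, 19.67% and 26.386% of the counts in control no-DT replicates 1 to 4, so the Hba-a1 term rests in part on that baseline. The higher call of the erythroid list by camera (adjusted p = 0.0133) was lost without replicates 3 and 4 of that group (0.2552). Without control no-DT replicate 4, where Cadps2 was at 2060 CPM against 34.7 to 334 in the other 3, the terms were 2.69 for Cadps2 and 2.51 for Gprin1. Without control no-DT replicate 1 the counts were 3951 genes and 5 lists.

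At day 2 it differed in 1613 genes and 10 lists, or 1 list with an estimated correlation. The terms were 4.83 for Gprin1, 4.57 for Cadps2, 4.55 for Ccn2, 3.83 for Ccn1, 3.80 for Tagln, 2.19 for Ear2 (sharing reads), 2.10 for Retnlg, 1.84 for Camp and 1.10 for Clec1b, and −6.70 for Chrdl1, −5.84 for Fmo2, −5.49 for Adipoq, −5.45 for Igfbp5, −5.39 for Gdpd2, −5.31 for Grem1, −4.34 for Lepr, −3.61 for Cxcl12 and −2.28 for Kitl. Without control no-DT replicate 4 they were 2.65 for Gprin1 and 2.51 for Cadps2. Without control no-DT replicate 1 the counts were 3749 genes and 6 lists.

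At day 3, where the lane label differs too, it differed in 3056 genes and 12 lists, or 1 list with an estimated correlation. The terms were 5.55 for Tagln, 5.41 for Ccn2, 4.65 for Gprin1, 4.44 for Cadps2, 4.42 for Timp1, 3.93 for Ccl7, 3.04 for Postn, 2.70 for Ear2 (sharing reads), 2.24 for Ecscr and 2.01 for Tnni2. Lower ones were −6.63 for Gdpd2, −6.62 for Chrdl1, −6.32 for Cfd, which rests on 1 read in DTRADQ at day 3, −5.72 for Esm1, −5.37 for Adipoq, −4.92 for Igfbp5, −4.70 for Grem1, −4.40 for Lepr, −4.10 for Cxcl12, −2.81 for Hemgn, −2.67 for Rhag, −2.67 for Kitl, −1.36 for Kif11 and −1.14 for Rrm1. Without control no-DT replicate 4 they were 2.49 for Gprin1 and 2.39 for Cadps2.

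Of 256 Dixon tests at the 5% level, each on 1 quantity in 1 group of 4 libraries, 28 marked a library. The test takes the gap to the nearest of the other 3 over the range of all 4. Chance gives about 1 in 20, or 12.8, though the tests share libraries and are not independent. The ratio also passes small differences where the other 3 lie close together. DTRADQ no-DT replicate 4 had 3.192% mitochondrial counts (others 2.575% to 2.664%), Col1a1 at 219 CPM (28.6 to 43.6) and Bglap at 21.3 CPM (2.54 to 3.52). The muscle score was 0.742 in control day 1 replicate 1 (−0.009 to 0.04) and 2.683 in control day 2 replicate 2 (0.783 to 0.996). Myl1 was at 2.64 CPM (0.192 to 0.399) and 27.1 CPM (0.787 to 1.85) in those libraries, at 9.29 CPM in control no-DT replicate 4 (0.625 to 1.89), at 5.18 CPM in DTRADQ day 1 replicate 2 (0 to 0.381) and at 6.64 CPM in DTRADQ day 2 replicate 2 (0.0779 to 1.10). In DTRADQ day 2 replicate 1 Ccl2 was at 87.9 CPM (14.9 to 19.6), Cxcl1 at 73.1 CPM (0.524 to 1.55) and Egr1 at 20.8 CPM (2.97 to 4.49). In DTRADQ day 1 replicate 3 Ccl2 was at 157 CPM (64.6 to 79.3), Egr1 at 48.3 CPM (20.7 to 24.7) and Ccn1 at 13.4 CPM (9.27 to 9.51). In control day 3 replicate 3 Ccl2 was at 8.58 CPM (2.54 to 3.44) and Cxcl1 at 12.1 CPM (0 to 0.90). Control day 1 replicate 1 had Prg2 at 7630 CPM (3650 to 4300) and Tagln at 0.674 CPM (1.25 to 1.28), and control no-DT replicate 1 had Tagln at 0.486 CPM (1.10 to 1.19). Cadps2 was at 2060 CPM in control no-DT replicate 4 (34.7 to 334), Ccn1 at 1.10 CPM in control day 2 replicate 2 (0.459 to 0.517), Pparg at 22.2 CPM in control day 2 replicate 4 (15.7 to 16.3) and Mki67 at 793 CPM in control day 2 replicate 3 (616 to 642). Id1 was at 11.1 CPM in control day 1 replicate 3 (9.78 to 9.96), Bglap at 3.20 CPM in control day 3 replicate 2 (2.18 to 2.30) and Pnck at 21.2 CPM in DTRADQ day 1 replicate 1 (22.2 to 22.3).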

How the results depend on the processing

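The alternative without control no-DT replicates 3 and 4 was chosen after seeing the data, and the others before. Main values stand in parentheses. With only the groups compared the genes called were 0 for genotype without DT (3944), 1010 for genotype at day 1 (567), 2621 for genotype at day 2 (1238), 5143 for genotype at day 3 (3330), 449 for genotype by DT at day 1 (1793), 356 for genotype by DT at day 2 (1613), 1669 for genotype by DT at day 3 (3056), 890 for DT in controls at day 1 (4859), 646 for DT in controls at day 2 (4109), 860 for DT in controls at day 3 (4391), 1755 for DT in DTRADQ at day 1 (796) and 2192 for DT in DTRADQ at day 2 (1324). With only the groups compared the lists called were 2 for DT in controls at day 1 (1) and 2 for DT in controls at day 3 (1). With only the groups compared the log2 change took the other sign for Grem1 in genotype without DT at 0.01 (0.00) and Id1 in DT in controls at day 1 at 0.02 (−0.03). Without control no-DT replicates 3 and 4 the genes called were 1900 for genotype without DT (3944), 1340 for genotype at day 1 (567), 2887 for genotype at day 2 (1238), 3148 for DT in controls at day 1 (4859), 1899 for DT in DTRADQ at day 1 (796) and 2960 for DT in DTRADQ at day 2 (1324). Without control no-DT replicates 3 and 4 the lists called were 3 for DT in controls at day 1 (1), 3 for DT in controls at day 2 (1) and 4 for DT in controls at day 3 (1). Without control no-DT replicates 3 and 4 the log2 change took the other sign for Grem1 in genotype without DT at 0.05 (0.00), Pparg in genotype at day 2 at 0.01 (0.00), Col1a1 in genotype by DT at day 3 at −0.25 (0.95), Sp7 in DT in controls at day 1 at 0.27 (−0.14), Adipoq in DT in controls at day 2 at 0.04 (−0.53), Hbegf in DT in controls at day 2 at −0.10 (0.01), Id1 in DT in controls at day 2 at −0.03 (0.08) and Bglap in DT in controls at day 2 at 0.29 (−0.39). With voom and library weights the genes called were 2150 for genotype at day 1 (567), 3608 for genotype at day 2 (1238), 5724 for genotype at day 3 (3330), 3465 for genotype by DT at day 1 (1793), 3373 for genotype by DT at day 2 (1613), 4599 for genotype by DT at day 3 (3056), 2163 for DT in DTRADQ at day 1 (796), 2977 for DT in DTRADQ at day 2 (1324) and 6531 for DT in DTRADQ at day 3 (4264). With voom and library weights the lists called were 2 for DT in controls at day 1 (1), 2 for DT in controls at day 2 (1) and 2 for DT in controls at day 3 (1). With voom and library weights the log2 change took the other sign for Pparg in genotype at day 1 at −0.01 (0.10), Pparg in genotype by DT at day 2 at −0.03 (0.02), Hbegf in DT in controls at day 2 at −0.29 (0.01), Id1 in DT in controls at day 2 at −0.22 (0.08) and Bglap in DT in controls at day 2 at 0.17 (−0.39). With the muscle covariate the genes called were 295 for DT in DTRADQ at day 1 (796) and 763 for DT in DTRADQ at day 2 (1324). With the muscle covariate the lists called were 0 for genotype without DT (2). With the muscle covariate the log2 change took the other sign for Pparg in genotype without DT at 0.18 (−0.02), Grem1 in genotype without DT at 0.04 (0.00), Bglap in genotype at day 2 at 0.22 (−0.24), Myl1 in genotype at day 3 at −0.18 (4.70), Pparg in genotype at day 3 at 0.01 (−0.51), Bglap in genotype at day 3 at −0.80 (0.40), Pparg in genotype by DT at day 1 at −0.11 (0.13), Bglap in genotype by DT at day 1 at 0.47 (−0.28), Pparg in genotype by DT at day 2 at −0.40 (0.02), Col1a1 in genotype by DT at day 2 at 0.00 (−1.05), Bglap in genotype by DT at day 2 at 0.20 (−0.99), Sp7 in DT in controls at day 1 at 0.09 (−0.14) and Hbegf in DT in controls at day 2 at −0.05 (0.01). With an estimated correlation the lists called were 0 for genotype without DT (2), 7 for genotype at day 1 (16), 1 for genotype at day 2 (18), 1 for genotype at day 3 (19), 1 for genotype by DT at day 1 (8), 1 for genotype by DT at day 2 (10), 1 for genotype by DT at day 3 (12), 0 for DT in controls at day 1 (1), 0 for DT in controls at day 2 (1), 0 for DT in controls at day 3 (1), 4 for DT in DTRADQ at day 1 (18), 1 for DT in DTRADQ at day 2 (15) and 1 for DT in DTRADQ at day 3 (17). By fry the lists called were 1 for genotype without DT (2), 5 for genotype by DT at day 1 (8), 6 for genotype by DT at day 2 (10), 2 for DT in controls at day 2 (1) and 3 for DT in controls at day 3 (1). With no filter on low counts the lists called were 6 for genotype without DT (2), all 6 higher while the 2 lower lists lost their calls, 7 for genotype by DT at day 3 (12), 10 for DT in controls at day 1 (1), 12 for DT in controls at day 2 (1) and 10 for DT in controls at day 3 (1), of which 9, 11 and 10 were higher. Lists called higher and lower with no filter were 7 and 10 for genotype at day 2 (12 and 6), 1 and 8 for genotype by DT at day 1 (5 and 3), 1 and 8 at day 2 (6 and 4), 3 and 4 at day 3 (8 and 4), and 7 and 8 for DT in DTRADQ at day 1 (11 and 7). Of the list calls between genotypes, the muscle covariate ended that of osteoblast genes at day 3 (adjusted p = 0.0975) and the block that of adipocyte genes at day 2 (0.0515). Fry ended those of erythroid (0.4860), neutrophil precursor granule (0.2415), cell division (0.3775) and PPAR genes (0.0524) at day 1. It also ended those of endothelial (0.1771), eosinophil (0.0648), cholesterol synthesis (0.1726) and cell division genes (0.0514) at day 2. At day 3 it ended that of mature neutrophil genes (0.0552), and without DT that of eosinophil genes (0.0739). With only the groups compared the calls of adipocyte genes at days 1 and 2 (0.0949 and 0.0693) and of matrix and endothelial genes at day 2 (0.1018 and 0.1092) were lost. With voom and library weights those of adipocyte genes without DT (0.0625) and at day 2 (0.0992) and of ERK genes at day 2 (0.0834) were lost. Without control no-DT replicates 3 and 4 those of adipocyte genes without DT (0.1293) and of adipocyte (0.1126), ERK and endothelial genes (0.0661 for each) at day 2 were lost. By fry the higher lists were 6 for genotype at day 1 (10), 4 for genotype by DT at day 3 (8) and 4 for DT in DTRADQ at day 1 (11). For genotype by DT at day 1 the higher erythroid (0.4112), neutrophil precursor granule (0.3532), megakaryocyte (0.0597) and inflammatory lists (0.0706) lost their calls by fry. At day 2 the higher endothelial (0.2832), neutrophil precursor granule (0.1492), mature neutrophil (0.2778) and inflammatory lists (0.2396) and the lower cell division list (0.0959) did. With no filter on low counts the log2 change took the other sign for Pparg in genotype without DT at 0.03 (−0.02), Grem1 in genotype without DT at 0.05 (0.00), Pparg in genotype at day 2 at 0.01 (0.00), Pparg in genotype by DT at day 2 at −0.02 (0.02) and Id1 in DT in controls at day 1 at 0.02 (−0.03). With the replicate number as block the lists called were 0 for genotype without DT (2). With the replicate number as block the log2 change took the other sign for Bglap in genotype by DT at day 1 at 0.08 (−0.28) and Hbegf in DT in controls at day 2 at 0.00 (0.01). With DESeq2 size factors the log2 change took the other sign for Pparg in genotype at day 2 at 0.02 (0.00) and Hbegf in DT in controls at day 2 at −0.01 (0.01). By DESeq2 the log2 change took the other sign for Pparg in genotype at day 2 at 0.02 (0.00) and Hbegf in DT in controls at day 2 at 0.00 (0.01). Leaving out 1 library at a time, the genes called ranged from 2285 to 5939 for genotype without DT (3944), from 327 to 676 for genotype at day 1 (567), from 569 to 1477 for genotype at day 2 (1238), from 1253 to 3951 for genotype by DT at day 1 (1793), from 1136 to 3749 for genotype by DT at day 2 (1613), from 437 to 744 for DT in DTRADQ at day 1 (796) and from 545 to 1302 for DT in DTRADQ at day 2 (1324). Leaving out 1 library at a time, the lists called ranged from 0 to 3 for genotype without DT (2), from 5 to 11 for genotype by DT at day 1 (8), from 6 to 11 for genotype by DT at day 2 (10), from 0 to 2 for DT in controls at day 1 (1), from 1 to 2 for DT in controls at day 2 (1) and from 0 to 3 for DT in controls at day 3 (1). Log2 changes whose sign turned when 1 library was left out ranged from −0.18 to 0.16 for Pparg in genotype without DT (−0.02), from −0.16 to 0.07 for Grem1 in genotype without DT (0.00), from −0.23 to 0.12 for Id1 in genotype without DT (−0.11), from −0.54 to 1.11 for Bglap in genotype without DT (0.75), from −0.01 to 0.23 for Pparg in genotype at day 1 (0.10), from −0.07 to 0.13 for Pparg in genotype at day 2 (0.00), from −0.66 to 0.02 for Bglap in genotype at day 2 (−0.24), from −0.65 to 0.23 for Sp7 in genotype at day 3 (−0.21), from −0.24 to 0.63 for Bglap in genotype at day 3 (0.40), from −0.06 to 0.28 for Pparg in genotype by DT at day 1 (0.13), from −0.64 to 1.02 for Bglap in genotype by DT at day 1 (−0.28), from −0.17 to 0.18 for Pparg in genotype by DT at day 2 (0.02), from −1.45 to 0.13 for Col1a1 in genotype by DT at day 2 (−1.05), from −1.45 to 0.30 for Bglap in genotype by DT at day 2 (−0.99), from −0.98 to 0.94 for Bglap in genotype by DT at day 3 (−0.35), from −0.07 to 0.26 for Cxcl12 in DT in controls at day 1 (0.12), from −0.28 to 0.00 for Pparg in DT in controls at day 1 (−0.18), from −0.24 to 0.09 for Hbegf in DT in controls at day 1 (−0.08), from −0.15 to 0.21 for Id1 in DT in controls at day 1 (−0.03), from −0.65 to 0.21 for Sp7 in DT in controls at day 1 (−0.14), from −0.10 to 0.59 for Col1a1 in DT in controls at day 1 (0.16), from −0.30 to 0.22 for Hbegf in DT in controls at day 2 (0.01), from −0.04 to 0.31 for Id1 in DT in controls at day 2 (0.08), from −0.18 to 0.66 for Sp7 in DT in controls at day 3 (0.33) and from −0.02 to 0.67 for Col1a1 in DT in controls at day 3 (0.24). Of these genes only Myl1 at day 3 had passed, and the covariate, the mean of a list that holds it, removes its change by construction. For the other changes the cause was not tested, apart from fewer libraries or groups in a fit. Fits of only the groups compared called fewer genes in each listed contrast with control no-DT libraries and more in the other listed ones. Control no-DT replicates 1 to 4 had voom weights of 0.246, 1.69, 0.259 and 0.0848. The main fit shares 1 spread per gene over all 8 groups, so its adjusted p-values may be too small in contrasts with these libraries. DESeq2 size factors kept the counts of genes and lists called within 1.5 times. DESeq2 did so for the totals of genes, but higher genes numbered 244 for genotype at day 1 (129), 979 for genotype at day 2 (639) and 374 for DT in DTRADQ at day 1 (183). Over 331 named values, 328 had the same direction and side of the threshold with DESeq2, 328 with its size factors, 323 with no filter, 322 with the block, 311 with voom, 310 without control no-DT replicates 3 and 4, 302 with the covariate and 298 with only the groups compared. Of 3312 values with 1 library left out, 3180 did. Of 40 pairs of libraries with the same number 15 had a correlation above 0.1 (−0.157 to 0.355) and 15 were best with their own number. All 4 pairs lay above 0.1 only for genotype without DT and DT in controls at day 1, where with the block 4229 and 5105 genes were called and the side of the threshold changed for 0 named genes. A sex covariate was not run, since all mice were male. At these depths genes such as Sp7 and Hbegf near 1 CPM limit what can be detected.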

Other observations

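Lists of metabolic, stress and interferon genes were called beside the stromal loss. Most of their members did not pass, and each of these calls was lost with an estimated correlation. Of 21 PPAR and fatty acid oxidation genes 1, 4 and 7 rose at days 1, 2 and 3 and 1 fell at day 3, or 3, 9 and 8 rose and 1 fell when adjusted over the list alone (median 0.19, 0.28 and 0.23, adjusted p = 0.0027, 0.0015 and 0.0063, but adjusted p = 0.1932, 0.1726 and 0.2267 with an estimated correlation). Cpt1a, which carries fatty acids into mitochondria, changed by 0.68 and 0.69 at days 2 and 3, and Pdk4 by 1.67 at day 3. Of 20 hypoxia and glycolysis genes 2 and 4 rose and 1 and 1 fell at days 2 and 3, or 5 and 9 rose when adjusted over the list alone (median 0.31 and 0.36, adjusted p = 0.0020 and 0.0014, but adjusted p = 0.1641 and 0.1601 with an estimated correlation). Adm, adrenomedullin, changed by 1.83 and 2.98 and P4ha2, a collagen prolyl hydroxylase, by 1.59 and 2.64. At day 3, 5 of 19 cholesterol synthesis genes rose, or 6 when adjusted over the list alone (median 0.37, adjusted p = 0.0021, but adjusted p = 0.3105 with an estimated correlation). Of 19 unfolded protein and integrated stress response genes 4 rose and 1 fell, or 4 and 2 when adjusted over the list alone (median 0.28, adjusted p = 0.0218, but adjusted p = 0.2267 with an estimated correlation), with Trib3 at 1.43. Of 25 type I interferon response genes 8 rose and 2 fell, or 9 and 2 when adjusted over the list alone (median 0.39, adjusted p = 0.0031, but adjusted p = 0.3716 with an estimated correlation), with Oas2 at 1.42 and Cmpk2 at −0.77. Skeletal muscle genes rose in the same libraries at day 3 (median 2.14).

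Tnfrsf11b, osteoprotegerin, the decoy receptor of RANKL, was at 8.50 ± 2.42 CPM in DTRADQ and 0.161 ± 0.123 CPM in controls at day 3 (log2 change 5.68, SE 0.61, adjusted p = 5.3e-08), a gene named after its values were seen. Its list of RANKL, OPG and WNT regulators had 6 that rose and 5 that fell at day 3, or 6 and 6 when adjusted over the list alone (median 0.17, adjusted p = 0.6076), and 1 that rose and 4 that fell at day 2, or 1 and 5 (median −0.19, adjusted p = 0.0913). Of 15 adipocyte genes 4 fell on each day and 1 rose at days 2 and 3, or 7, 5 and 5 fell and 1 rose each day when adjusted over the list alone (median 0.05, −0.22 and −0.18, mean −1.15, −1.27 and −1.39, adjusted p = 0.0156, 0.0446 and 0.2432, and adjusted p = 0.1932, 0.3288 and 0.4863 with an estimated correlation). At day 1 the median has the other sign from the mean and the test. The adipocyte call was lost at day 1 without DTRADQ replicate 1 (adjusted p = 0.0535) or control replicate 3 (0.0689) and at day 2 without DTRADQ replicate 1 (0.0754) or 2 (0.0525) or control replicate 2 (0.0649). Of 18 ERK response genes 3 rose at day 2, or 5 with 1 that fell when adjusted over the list alone (median 0.39, adjusted p = 0.0359), and 4 rose at day 3, or 6 (median 0.45, adjusted p = 0.0037), with Etv5 at 1.21 at day 3. With an estimated correlation these had adjusted p = 0.1447 and adjusted p = 0.0598, and the call at day 2 was lost without DTRADQ replicate 1 (adjusted p = 0.0754) or control replicate 1 (0.0633) or 4 (0.0594) and with no filter on low counts (0.2756).

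Further lists were called between genotypes with the preset correlation and lost with an estimated one. At day 1 erythroid genes (0 of 26 passed, median 0.21, adjusted p = 0.0074, but adjusted p = 0.6892 with an estimated correlation), cell division genes (0 of 22, median 0.12, adjusted p = 0.0145, but adjusted p = 0.6457 with an estimated correlation) and neutrophil precursor granule genes (0 of 17, or 2 that rose when adjusted over the list alone, median 0.49, adjusted p = 0.0018, but adjusted p = 0.4780 with an estimated correlation) were called by camera. The erythroid call was lost without DTRADQ replicate 4 (adjusted p = 0.0862) or control replicate 1 (0.2894), and that of cell division without DTRADQ replicate 1 (0.0747) or control replicate 1 (0.1609). At day 2 basophil, mast cell and eosinophil genes (0 of 17, median 0.46, adjusted p = 0.0043, but adjusted p = 0.3298 with an estimated correlation), cell division genes (0 of 22, median −0.23, adjusted p = 0.0046, but adjusted p = 0.4413 with an estimated correlation), cholesterol synthesis genes (1 of 19 rose, 0 when adjusted over the list alone, median 0.21, adjusted p = 0.0142, but adjusted p = 0.4460 with an estimated correlation) and stem and progenitor genes (5 of 18 rose and 1 fell, or 8 and 1 when adjusted over the list alone, median 0.30, adjusted p = 0.0096, but adjusted p = 0.1049 with an estimated correlation) were called. The cholesterol call was lost without control replicate 4 (adjusted p = 0.0562) and with no filter on low counts (0.0843), as was that of stem and progenitor genes with no filter (0.0557). At day 3 stem and progenitor genes (4 rose and 2 fell, or 7 and 2 when adjusted over the list alone, median 0.30, adjusted p = 0.0211, but adjusted p = 0.0815 with an estimated correlation) and mature neutrophil genes (6 of 22 rose and 1 fell, or 7 and 1 when adjusted over the list alone, median 0.41, adjusted p = 0.0061, but adjusted p = 0.3716 with an estimated correlation) were called, the latter not without control replicate 4 (adjusted p = 0.0789) and the former not with no filter on low counts (adjusted p = 0.0634).

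Lists that were not called at day 3 were monocyte and macrophage genes (3 of 26 rose and 2 fell, median 0.14, adjusted p = 0.2080), plasma cell genes (1 of 11 rose, median −0.07, adjusted p = 0.5354), B lineage genes (2 of 25 rose and 4 fell, median 0.17, adjusted p = 0.5669), T and NK cell genes (6 of 22 rose, median 0.02, adjusted p = 0.0592), osteoclast genes (3 of 12 rose and 1 fell, median 0.39, adjusted p = 0.1680), BMP antagonists (2 of 11 rose and 3 fell, median −0.20, adjusted p = 0.1680), BMP and SMAD target genes (1 of 9 fell, median 0.26, adjusted p = 0.5337), EGF receptor family and ligands (2 of 5 fell, median 0.04, adjusted p = 0.6953), glucocorticoid response genes (5 of 20 rose and 3 fell, median 0.00, adjusted p = 0.2155), p53 target genes (6 of 19 rose and 2 fell, median 0.12, adjusted p = 0.1326) and neutrophil precursor granule genes (1 of 17 rose, median 0.05, adjusted p = 0.4854). When adjusted over the list alone the counts that rose and fell were 2 and 2, 1 and 0, 2 and 4, 6 and 0, 3 and 1, 3 and 3, 0 and 1, 1 and 2, 5 and 3, 6 and 3, and 1 and 0 in that order. The chondrocyte list had 4 tested genes and was not tested as a list, and 1 of them rose at day 3, also 1 when adjusted over the list alone (median 0.72).

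The fall of erythroid genes at day 3 was looked at in 2 further ways fixed before their results were seen. With 9 globin genes left out of the scaling 21 erythroid genes fell (median −1.78), but no log2 change shifted by more than 0.00066, so this setting moved nothing and decides nothing. Over 381 genes matched to the list for length and expression, 20 per list gene before removing repeats, the median was 0.02, against −1.72 for the list.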
